A study of Mus musculus with 12 samples.

How the data were processed

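RNA was measured by sequencing in 12 left ventricle samples of C57BL/6J mice, 4 per group, taken 3 days after 2 intramyocardial injections of 10 µl of PBS, Upy-PEG or Upy-PEG with antimiR-195. Per the labels, snap-frozen tissue was extracted with TRIzol and libraries were made from polyadenylated RNA with a TruSeq stranded mRNA kit. Per the submitters' processing notes, reads were aligned to GRCm38 with STAR and reads per gene were counted with HTSeq, which gave the deposited read count of each gene in each library. Per the submitters' processing notes the authors used DESeq for differential expression, and versions of these tools and of the gene annotation are not given in the sources used. The deposited RPKM table holds the authors' reads per kilobase of gene per total reads, and dividing its values into the counts gave 1 length per gene for 23961 genes, the same in every library (largest relative spread 4.9e-14).

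The deposited files hold 38293 genes. The count table of the series equalled the per-sample count files in 459516 of 459516 cells compared. The counts in the special categories of HTSeq were left out of the gene table: reads on no gene were 6.25% to 8.77% of uniquely aligned reads, ambiguous reads 0.66% to 0.9%, and alignments of multi-mapped reads 0.579 to 0.921 per counted read. Counts come from uniquely assigned reads, so genes with near-identical copies, such as Hba-a1 and Hba-a2 or the ribosomal protein genes with pseudogenes, carry uncertain values, as do genes overlapping others on the same strand. Gene totals averaged 26.13 ± 2.82 × 10⁶ in PBS, 26.98 ± 1.54 × 10⁶ in Upy-PEG and 23.82 ± 1.37 × 10⁶ in antimiR-195 libraries (SD, n = 4). Symbols and coordinates came from GENCODE release 21 for the mouse, on GRCm38, which held 36429 of the gene IDs and 99.86% of the counted reads; 13 symbols belong to more than 1 gene ID.

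Gene tests used edgeR 4.0.16 (R 4.3.3, limma 3.58.1) on raw counts of all 12 libraries with filterByExpr by group, TMM normalisation, estimateDisp, glmQLFit and glmQLFTest, a model of group means with 9 residual degrees of freedom, and Benjamini-Hochberg adjustment over the 14770 genes tested at a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of the quasi-likelihood F. CPM are TMM-scaled counts with no prior count, and log2 CPM used a prior count of 2. The labels give no batch, sex, litter or pairing, and replicate numbers follow the order of deposition, so no covariate or pairing was used.

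In the same fit, 47 gene lists were tested with camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 45 lists with at least 3 tested members. Each list was also tested with camera with an estimated correlation and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. A count given as adjusted over the list alone is of members past 0.05 after adjustment within the list. Sites for the seed of miR-195 (8mer or 7mer-m8) were searched in the longest annotated 3' untranslated region of at least 20 bases, in 13309 genes. A site was found in 3296 genes, and 7242 genes had no 6-mer match. The shift is the median log2 fold change of genes with a site minus that of genes with no 6-mer match, within deciles of length. The deciles were averaged with weights by their number of genes with a site. The shift was tested with a 2-sided exact permutation test over the 70 assignments of 8 libraries. It was ranked among 190 other 7-mers of the same base composition with sites in at least 200 genes, a minimum set after rarer 7-mers gave no value. Agreement between comparisons is the Pearson r and covariance of log2 fold changes across genes, against 20 simulations of unchanged groups.

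The groups, comparisons, tests, gene lists, other settings to try and the rule for naming genes were fixed before the data were examined. The rule named genes past the threshold and, since fewer than 5 passed in each comparison, the 5 of each sign with the lowest p, given as values that did not pass, plus 21 markers in every comparison. As no gene passed, the 3 members of each called list with the lowest p were added after the values were seen. Further list members were named then where 5 or fewer passed when adjusted over the list alone. Retnla, Ccl24, Timp3, Timp4 and Arntl, which passed against the direction of their lists, were named then too. Some genes that these rules name are not reported here. The other settings fixed beforehand were RLE size factors, no filter, a mean CPM of at least 1, DESeq2 1.42.0, limma voom with sample weights, limma-trend on log2(RPKM + 0.1), only the 8 libraries compared, an adjusted p under 0.10, both hydrogel groups against PBS, other site definitions, a mean CPM of at least 10, and leaving out each library in turn. Settings added after the data were seen left out antimiR-195 replicates 2 and 3 together, took each library's gene length slope as a covariate, used a gene length offset, library size alone or the upper quartile, and split the Upy-PEG libraries between comparisons.

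The edgeR gene test was checked on counts simulated from the means and library sizes of the 14770 genes, with 200 changed. For Upy-PEG against PBS the edgeR fit recovered 25.4% of genes changed 1.5-fold, 65.7% changed 2-fold and 93.9% changed 4-fold, with 7 false calls among 130. For the antimiR-195 group it recovered 19.4%, 82.1% and 95.5% against Upy-PEG, and 25.4%, 74.6% and 95.5% against PBS. Each gene was drawn independently around 1 mean, without the structure among libraries seen in the real data. These shares can therefore overstate the recovery in the real data. A list of 20 genes raised 1.5-fold was called and 0 of 199 unchanged lists were, with genes simulated as independent. A seed shift of 0.1 on the log2 scale, added to independent random values, was recovered as 0.1 over 10 simulations of 13309 genes. That checks only the arithmetic of the estimate. A simulated covariance of 0.0717 was recovered as 0.0727 over 9378 genes. Camera with an estimated correlation and fry were not checked on simulated data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps. No library was left out of the reported values, and no per-sample value column went unused.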

Results

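Polyadenylated RNA was sequenced from the left ventricle of healthy C57BL/6J mice 3 days after 2 injections of 10 µl each into the heart muscle. The 12 libraries formed 3 groups of 4: hearts injected with phosphate-buffered saline (PBS), with Upy-PEG, and with Upy-PEG carrying antimiR-195. Upy-PEG is a hydrogel of poly(ethylene glycol) chains held together by hydrogen bonds between ureidopyrimidinone groups, and antimiR-195 is an oligonucleotide that blocks miR-195, a microRNA of the miR-15 family that restrains the cell cycle of heart muscle cells. The PBS libraries held 30.3, 24.9, 24.1 and 25.2 × 10⁶ counts on genes, the Upy-PEG libraries 28.2, 28.2, 25.0 and 26.5 × 10⁶, and the antimiR-195 libraries 23.2, 24.1, 22.4 and 25.6 × 10⁶. Between 18668 and 19740 genes had at least 1 count in a library, and 14770 genes passed the filter and were tested. The labels list the libraries as separate samples and do not say that each came from a separate animal, so each p measures the spread between these samples.

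The libraries differed among themselves in ways the groups did not explain. The first principal component held 35.1% of the variance and set antimiR-195 replicates 2 and 3 at −60.2 and −40.7, with the other libraries between −8.5 and 33.4. Those libraries also had lower values for long genes, by −0.229 and −0.135 log2 per doubling of gene length, against −0.042 to 0.122 elsewhere. Across 14770 genes, which are not independent replicates, the loading on this component and log2 gene length had a Pearson r of 0.51. Upy-PEG replicate 1 stood highest on the second component, at 47.5, and its interferon response genes averaged 1.08 log2 above the mean of all libraries, against −0.131 to 0.076 in the other Upy-PEG libraries. PBS replicate 1 carried 12.3% of its counts on mitochondrially encoded genes, against 18.7% to 19.5% in the other PBS libraries.

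**Figure D1:**
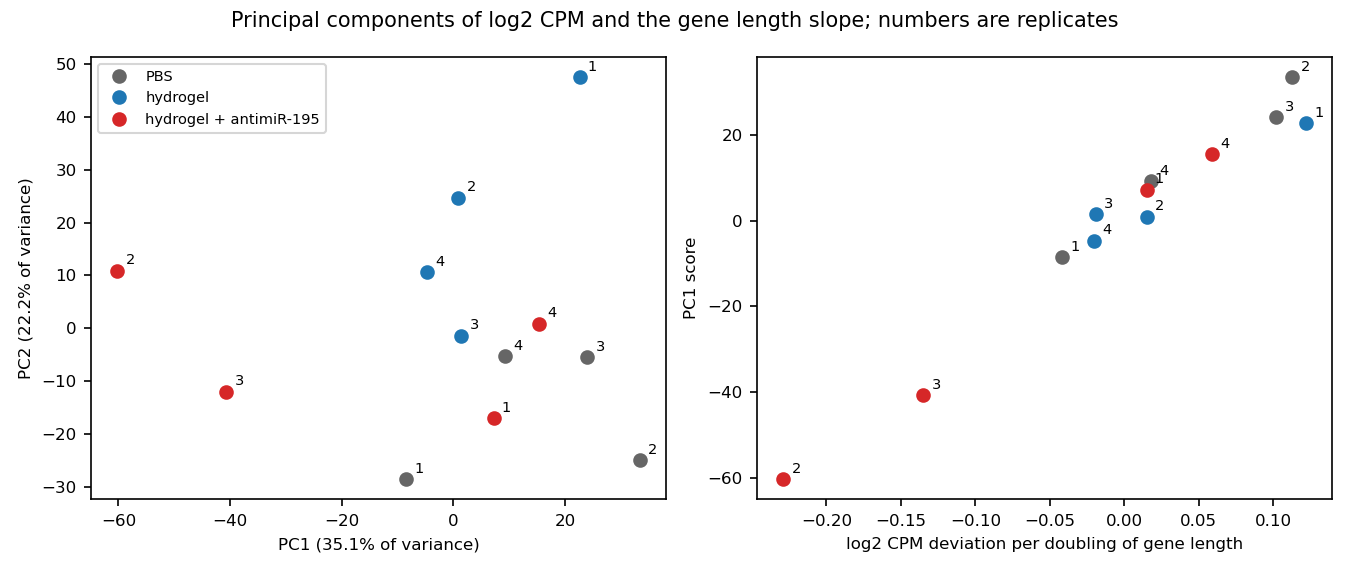
Scores of the 12 libraries on the first 2 principal components of log2 CPM, with the percent of variance on each axis, and each library's slope of log2 CPM on log2 gene length against its first component score. AntimiR-195 replicates 2 and 3 sit at −60.2 and −40.7 on the first component and have the most negative slopes, −0.229 and −0.135.

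The comparison of Upy-PEG with PBS asks what the hydrogel itself adds to the injection. Genes of macrophages, scavenger cells that take up foreign material, rose with the hydrogel, with a median fold of 1.83 over 20 markers and 19 of 20 higher (camera, adjusted p = 1.22e-22, and adjusted p = 0.158 with an estimated correlation). Genes of macrophage fusion and foreign-body giant cells rose further, with a median fold of 2.45 and 10 of 10 higher (adjusted p = 6.08e-14, and 0.158 with an estimated correlation). Adjusted over the list alone, 17 of the 20 macrophage markers and 9 of the 10 fusion genes passed with higher values, but no gene passed 0.05 over all genes in edgeR. Cd68 (ENSMUSG00000018774, GRCm38 chromosome 11, 69664213 to 69666153), a lysosomal glycoprotein of macrophages, measured 61.4 ± 7.97 CPM (counts scaled to library size) with Upy-PEG and 26.3 ± 7.98 with PBS (SD, n = 4 each), a log2 fold change of 1.22 ± 0.193 (SE, edgeR adjusted p = 0.0809). Gpnmb (chromosome 6, 49036546 to 49070929), a glycoprotein of lipid-laden and fusing macrophages, had a log2 fold change of 1.42 ± 0.299 (adjusted p = 0.0971), and the elastase gene Mmp12 1.79 ± 0.339 (adjusted p = 0.0971). Adgre1, which encodes F4/80, stood at 0.91, Lgals3 at 1.59 and the proton pump subunit gene Atp6v0d2 at 1.43 on the log2 scale. Lysosome genes rose by a median fold of 1.27 (20 of 22 higher, 12 adjusted over the list alone, adjusted p = 7.83e-11, and 0.158 with an estimated correlation), among them Ctsb at a log2 fold change of 0.62 and Grn at 0.59. Of the macrophage markers, 2 are also in the fusion list and 2 in the list of alternative activation.

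Inflammatory signals rose with the hydrogel as well. Cytokine and chemokine genes had a median fold of 1.67, with 23 of 24 higher and 14 passing when adjusted over the list alone (camera, adjusted p = 1.19e-13, and 0.158 with an estimated correlation). The chemokine genes Ccl3 and Ccl7, which draw in monocytes, had log2 fold changes of 1.72 ± 0.406 and 1.32 ± 0.338 (SE, n = 4 per group), and the interleukin 1 receptor antagonist Il1rn 1.38 ± 0.253. Il1b stood at 0.37, Il6 at 0.73 and S100a8 at 0.84, with SEs of 0.343, 0.522 and 0.526. Il1b was 0.245 and 0.699 without PBS replicates 2 and 4, Il6 1.536 without PBS replicate 3, and S100a8 1.322 without PBS replicate 4 and 0.411 without Upy-PEG replicate 3. Monocyte markers rose by a median fold of 1.68 (adjusted p = 0.00177, and 0.3 with an estimated correlation), with Ccr2 at 1.06, Chil3 at 1.30 and, lower, Nr4a1 at −1.15 passing when adjusted over the list alone. Neutrophil markers rose by 1.65 (9 of 9 higher, adjusted p = 0.000971, and 0.277 with an estimated correlation), and Mmp8 alone, at 1.42, passed when adjusted over the list alone. Complement genes rose by 1.10 (adjusted p = 0.00334, and 0.255 with an estimated correlation), through the receptor genes C3ar1 at 1.13 and C5ar1 at 0.80 and properdin, Cfp, at 0.65, the 3 that passed when adjusted over the list alone. Interferon response genes rose by 1.46 (28 of 28 higher, adjusted p = 1.08e-07, and 0.395 with an estimated correlation), and 0 of 28 passed when adjusted over the list alone. Genes of alternative macrophage activation rose by 1.27 (adjusted p = 0.0444, and 0.395 with an estimated correlation) with members on both sides: Chil3, Mrc1, Il4ra and Igf1 were higher and Retnla (−1.22) and Ccl24 (−0.84) lower when adjusted over the list alone.

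Single libraries set the size of several of these inflammatory values. Chil3 was 2.06 without PBS replicate 4. The call for alternative activation ended without PBS replicate 1, 2 or 3 (adjusted p = 0.0527, 0.087 and 0.0696) and without Upy-PEG replicate 1, 2 or 4 (0.0587, 0.0763 and 0.123), with log2 medians from 0.23 to 0.42. Without Upy-PEG replicate 1 the interferon median fell to 0.114 and the monocyte median to 0.38 on the log2 scale, from 0.548 and 0.748, and both lists stayed past the threshold. The neutrophil median of 0.719 became 1.139 without PBS replicate 4 and 0.426 without Upy-PEG replicate 3. The complement median of 0.132 became 0.081, 0.067, 0.052 and 0.221 without PBS replicates 1, 2, 3 and 4 in turn, and 0.029 without Upy-PEG replicate 4. In settings chosen after the data were seen, the call for alternative activation ended with each library's gene length slope as a covariate (log2 median 0.309, adjusted p = 0.0606) and without antimiR-195 replicates 2 and 3 in the shared fit (0.348, 0.0854). The complement median was 0.085 without those 2 libraries.

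Genes of scar formation rose with the hydrogel. Extracellular matrix genes had a median fold of 1.72, with 35 of 36 higher and 29 passing when adjusted over the list alone (camera, adjusted p = 1.2e-22, and 0.167 with an estimated correlation). Their mean log2 CPM deviation was 1.032, 0.675, −0.103 and 0.162 in Upy-PEG replicates 1 to 4. Replicate 3 thus lay inside the PBS range of −0.573 to −0.064 (2-sided exact permutation p of the list mean 0.0857). Genes of myofibroblasts, the contractile fibroblasts of healing wounds, had a median fold of 2.0 (12 of 14 higher, 9 adjusted over the list alone, adjusted p = 4.38e-10, and 0.158 with an estimated correlation). Postn (ENSMUSG00000027750, chromosome 3, 54361109 to 54391037), the matrix protein periostin, had a log2 fold change of 1.66 ± 0.365 (SE, n = 4 per group, edgeR adjusted p = 0.0971). Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), the main fibrillar collagen, measured 1690 ± 708 CPM with Upy-PEG and 886 ± 212 with PBS (SD, n = 4 each, edgeR adjusted p = 0.144). Mfap4 and Mfap5, proteins of elastic fibres, stood at 1.10 and 0.91, and the fibroblast activation genes Ltbp2 and Meox1 at 1.47 and 1.11 on the log2 scale. Matrix proteases and their inhibitors rose by a median fold of 1.57 (adjusted p = 4.33e-07, and 0.158 with an estimated correlation). Adjusted over the list alone, 10 of these 18 genes passed with higher values, Mmp12, Mmp14 and Adam8 among them, and the inhibitors Timp3 (−0.57) and Timp4 (−0.71) with lower ones. Ltbp2 was 0.975 without Upy-PEG replicate 1, and Timp4 −1.106 without Upy-PEG replicate 4. Markers of resting fibroblasts had a median fold of 1.07 and were not called (adjusted p = 0.164).

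Genes of the cell cycle gave the lowest p of any list. Mitotic and replication genes rose by a median fold of 2.05, with 35 of 35 higher and 32 passing when adjusted over the list alone (camera, adjusted p = 1.03e-31, and 0.158 with an estimated correlation). Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), a protein of dividing nuclei, measured 28.4 ± 11 CPM with Upy-PEG and 12.1 ± 3.8 with PBS (SD, n = 4 each), a log2 fold change of 1.23 ± 0.268 (edgeR adjusted p = 0.0971). The checkpoint kinase Bub1 and the kinesin Kif20a stood at 1.51 and 1.04 on the log2 scale. These tissue values do not say which cells divided.

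Genes of cardiomyocyte stress rose and genes of the working cardiomyocyte fell, as shares of the counts of whole tissue. Such values do not separate a change within cells from a change in the mix of cells. The hypertrophic and stress list rose by a median fold of 1.28 (13 of 16 higher, camera, adjusted p = 4.1e-05, and 0.158 with an estimated correlation). Nppa (ENSMUSG00000041616, chromosome 4, 148000722 to 148002079), which encodes atrial natriuretic peptide, measured 975 ± 305 CPM with Upy-PEG and 322 ± 66 with PBS (SD, n = 4 each), a log2 fold change of 1.60 ± 0.274 (edgeR adjusted p = 0.0914). Nppb (ENSMUSG00000029019, chromosome 4, 147985788 to 147987205), the B-type peptide, had a log2 fold change of 0.72 ± 0.254, while Myh7 stood at 0.27 ± 0.364 and Ankrd1 at 0.06 ± 0.218. With 1 library left out Myh7 ran from 0.045 (without PBS replicate 2) to 0.446 (without Upy-PEG replicate 1), and Ankrd1 from −0.072 (without PBS replicate 2) to 0.263 (without PBS replicate 1). Adjusted over the list alone, 7 of the stress genes passed with higher values, Fhl1 and Tnfrsf12a among them, and 1 with a lower value. Genes of the unfolded protein and integrated stress response rose by 1.19 (6 of 21 adjusted over the list alone, adjusted p = 0.000182, and 0.242 with an estimated correlation), with Sdf2l1 at 0.755 and Mthfd2 at 0.87. Ribosomal protein genes rose by 1.13 (30 of 30 higher, 0 adjusted over the list alone, adjusted p = 0.00237, and 0.621 with an estimated correlation). Without PBS replicate 2 their call ended (log2 median 0.1, adjusted p = 0.0651), and without PBS replicate 1 the median rose from 0.17 to 0.285. Markers of skeletal muscle rose by 1.32 (adjusted p = 0.0237, and 0.158 with an estimated correlation), with the fast troponin gene Tnnt3 at 1.91 the only one of 7 to pass when adjusted over the list alone. That call ended without PBS replicate 3 (log2 median 0.32, adjusted p = 0.0674) or Upy-PEG replicate 3 (0.26, adjusted p = 0.122). It also ended without antimiR-195 replicates 2 and 3 in the fit (0.322, adjusted p = 0.061), a setting chosen after the data were seen.

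Cardiomyocyte markers fell to a median fold of 0.821, with 20 of 20 lower (camera, adjusted p = 2.1e-05, and 0.258 with an estimated correlation), led by the main adult myosin Myh6 at −0.42 ± 0.17 and the creatine kinase Ckm at −0.38 ± 0.189 (log2, SE, n = 4 per group). Genes of fatty acid oxidation, the main fuel of the heart, fell to 0.825 (28 of 29 lower, adjusted p = 4.25e-07, and 0.288 with an estimated correlation), and nuclear genes of oxidative phosphorylation to 0.865 (42 of 42 lower, adjusted p = 7.69e-06, and 0.527 with an estimated correlation). Ion channel and calcium handling genes fell to 0.855 (22 of 26 lower, adjusted p = 0.00532, and 0.418 with an estimated correlation) and endothelial markers to 0.914 (16 of 18 lower, adjusted p = 0.0153, and 0.324 with an estimated correlation), with Flt1 at −0.38 and Tie1 at −0.29. In these 5 lists, 0 members passed when adjusted over the list alone. Erythroid genes fell to 0.522 (10 of 10 lower, adjusted p = 1.54e-05, and 0.258 with an estimated correlation), with Alas2 (−0.99) among those passing when adjusted over the list alone. Only 3 of the 10 adipocyte markers were tested, and they fell to a median fold of 0.404 (adjusted p = 0.0237, and 0.242 with an estimated correlation) through Car3 (−1.34) and Cfd (−1.31), which passed when adjusted over the list alone.

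Several of the falls rested on single libraries. The call ended for oxidative phosphorylation without Upy-PEG replicate 1 (log2 median −0.07, adjusted p = 0.0505), for ion channels without PBS replicate 2 (−0.13, 0.0518), for endothelial markers without PBS replicate 1 (−0.07, 0.25), and for adipocyte markers without PBS replicate 4 (−1.17, 0.0725) or Upy-PEG replicate 1 (−1.18, 0.0587). Without Upy-PEG replicate 1 the log2 medians of the cardiomyocyte and fatty acid oxidation lists, −0.285 and −0.278, became −0.149 and −0.154, and Ckm became −0.238. Without PBS replicate 1 those of the erythroid and oxidative phosphorylation lists, −0.939 and −0.21, became −0.456 and −0.108, with Alas2 at −0.639, and both lists stayed past the threshold. In settings chosen after the data were seen, the adipocyte call ended with the gene length covariate (−1.288, 0.0606) and without antimiR-195 replicates 2 and 3 in the fit (−0.982, 0.0548). The ion channel median moved from −0.227 to −0.139 with the covariate. Under library size alone in place of TMM, chosen then too, medians of log2 CPM differences shrank. They moved from −0.254 to −0.154 for cardiomyocyte, −0.195 to −0.095 for ion channel and −0.134 to −0.034 for endothelial genes.

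Circadian clock genes, the transcription factors of the daily rhythm and their outputs, fell to a median fold of 0.722 with 15 of 17 lower (camera, adjusted p = 9.93e-06, and 0.158 with an estimated correlation). Adjusted over the list alone, 8 passed with lower values and Arntl, which encodes the positive factor BMAL1, with a higher one (1.53). Per1 (ENSMUSG00000020893, chromosome 11, 69095217 to 69109960), a repressor of the clock, measured 52.3 ± 11.8 CPM with Upy-PEG and 88.5 ± 8.02 with PBS (SD, n = 4 each), a log2 fold change of −0.76 ± 0.209 (edgeR adjusted p = 0.123). Hlf, an output of the clock, stood at −0.65. Without Upy-PEG replicate 1 the list's log2 median moved from −0.47 to −0.313.

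Over all genes, edgeR called 0 of 14770 at an adjusted p of 0.05 between Upy-PEG and PBS, with a smallest adjusted p of 0.0809 and 1944 genes at an unadjusted p under 0.05, 1378 higher and 566 lower, where chance gives 738 on average. That average does not give the spread around it. The highest other split of the same 8 libraries into 4 and 4 gave 1807 genes at this threshold. Library size alone, a setting chosen after the data were seen, gave 2095 such genes, with 91.7% higher against 70.9%. On the same libraries DESeq2 called 518 genes and limma voom with sample weights 918, and edgeR called 46 without Upy-PEG replicate 3. The values of the 2 groups did not overlap for 1430 genes, or 9.7%, where chance gives 2.9%. Apobec1, Gdf3, Ly9 and Alcam, with log2 fold changes of 1.04, 1.91, 1.43 and 1.02, joined Cd68 as the 5 higher genes with the lowest p, and Rasgrp2, Gm4956, Kcnn2, Rapgef3 and Kank3, at −0.545, −1.28, −0.48, −0.405 and −0.485, were the 5 lower ones. Of the 45 lists tested, camera called 25, 17 higher and 8 lower, and 18 of the 25 stayed called when any 1 of the 8 libraries compared was left out. None passed with an estimated correlation, where the lowest adjusted p was 0.158. A 2-sided exact permutation test of each list's mean over the 8 libraries, unadjusted, put 13 of the 45 lists under 0.05. Glycolysis and hypoxia genes, which camera did not call, were among them (exact permutation p = 0.0286). Called lists above 0.05 in this test included cardiomyocyte (0.0571), extracellular matrix (0.0857), interferon (0.171), ribosomal protein (0.229) and oxidative phosphorylation genes (0.343). With fry 7 lists passed, each at an adjusted p of 0.0383: macrophage, macrophage fusion, lysosome, matrix protease, mitotic, skeletal muscle and clock genes.

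**Figure D2:**
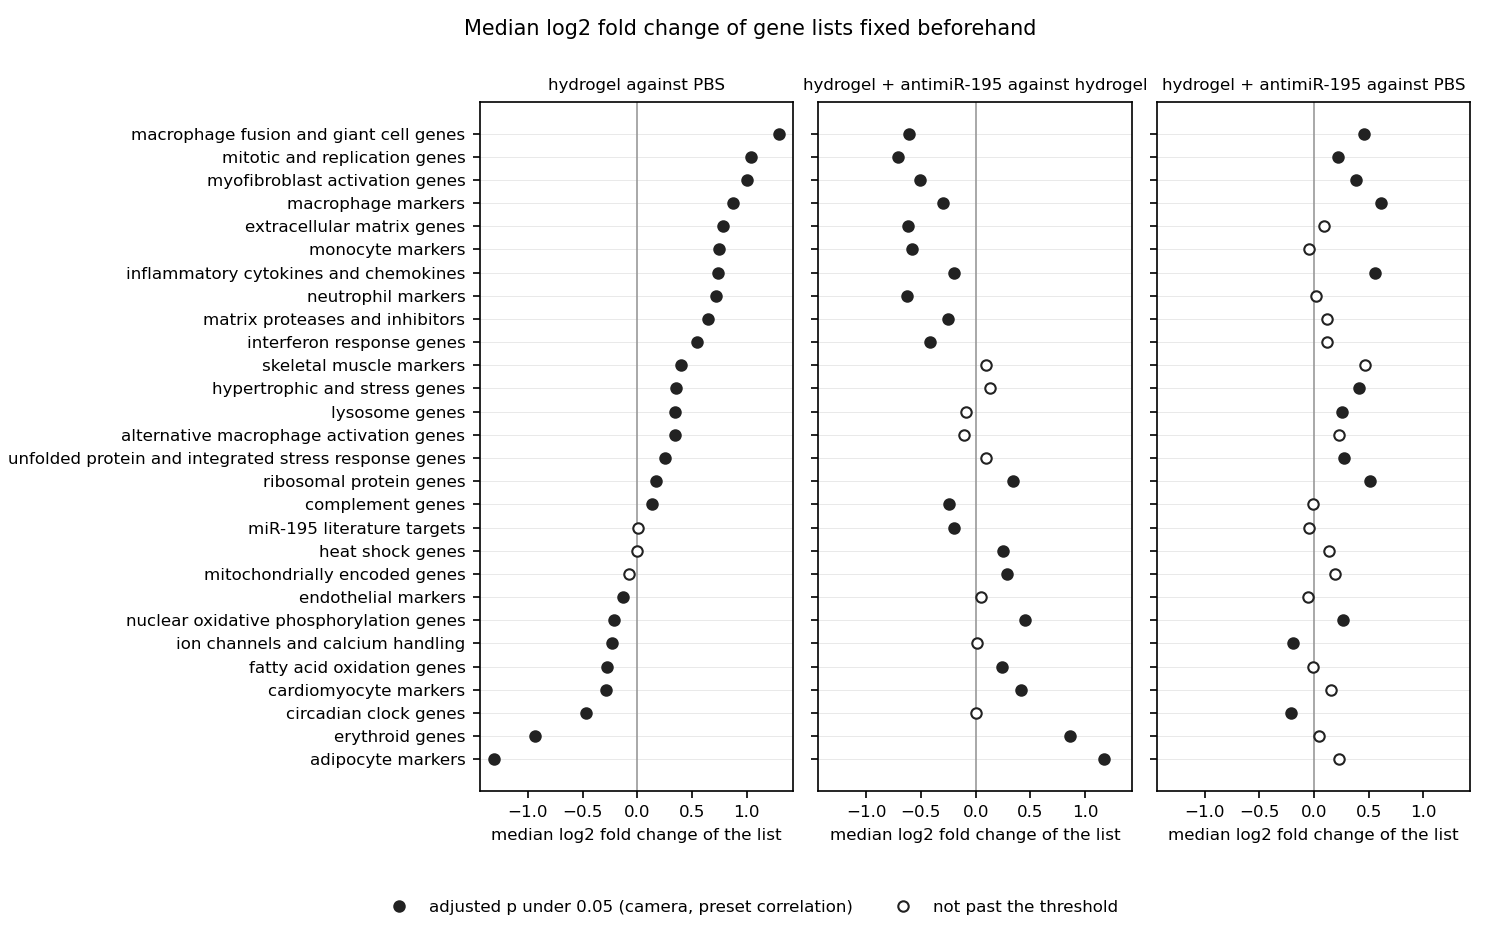
Median log2 fold change of each of the 28 gene lists called in at least 1 comparison, with 1 panel per comparison; filled points had a camera adjusted p under 0.05. Mitotic genes stand at 1.04 with Upy-PEG against PBS, −0.71 when the antimiR was added to the hydrogel, and 0.22 with both against PBS.

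The other 20 lists were not called between Upy-PEG and PBS, at adjusted p from 0.0579 for p53 targets to 0.962 for atrial markers. Median log2 fold changes were 0.435 for T cell markers, 0.25 for B cell markers, 0.35 for dendritic cell and MHC class II genes, and −0.15 for mast cell markers. Vascular lists stood at −0.01 for angiogenesis genes, 0.05 for lymphatic endothelium and −0.16 for smooth muscle and pericytes. They were 0.10 for fibroblast, −0.10 for epicardial, −0.20 for atrial, −0.20 for Schwann cell and −0.14 for thymocyte markers. Glycolysis and hypoxia genes stood at 0.05, p53 targets at 0.14, glucocorticoid response genes at −0.17, immediate early genes at 0.075, heat shock genes at −0.004, mitochondrially encoded genes at −0.08 and sex-linked genes at −0.02. The median had another sign than the mean or the test for atrial, epicardial, heat shock and thymocyte genes. Natural killer cell and lung markers had 2 and 1 tested members and were not tested as lists.

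The comparison of the antimiR-195 group with Upy-PEG asks what the antimiR adds when the hydrogel is held fixed. Of the 17 lists that had risen with the hydrogel, 11 were called lower with the antimiR by camera at its preset correlation. With an estimated correlation or with fry, 0 of these 11 were. Both comparisons use the same Upy-PEG libraries, which alone gave a covariance of −0.0284 across genes in simulations of unchanged groups. Mitotic and replication genes fell to a median fold of 0.611, with 34 of 35 lower and 16 passing when adjusted over the list alone (camera, adjusted p = 6.87e-18, and 0.525 with an estimated correlation). Extracellular matrix genes fell to 0.65, with 34 of 36 lower and 18 passing when adjusted over the list alone (adjusted p = 1.56e-15, and 0.525 with an estimated correlation). No gene passed 0.05 over all genes in edgeR, so the values of single genes are given as values only. Mki67 measured 11.5 ± 2.23 CPM with the antimiR and 28.4 ± 11 without it (SD, n = 4 each), a log2 fold change of −1.31 ± 0.27 (SE, edgeR adjusted p = 0.364). Brca1, Ccnf and Bub1b, which act in DNA repair and mitosis, stood at −1.485, −1.30 and −1.07 on the log2 scale. Col1a1 measured 724 ± 170 CPM with the antimiR (SD, n = 4), a log2 fold change of −1.225 ± 0.277 (edgeR adjusted p = 0.364), with Col5a1 at −0.98 and Thbs2 at −0.66. Without Upy-PEG replicate 1 the matrix median moved from −0.622 to −0.386 on the log2 scale. Of the other 6 lists, ribosomal protein genes were called higher, as given below, and 5 were not called. Hypertrophic, unfolded protein and skeletal muscle lists stood at median folds of 1.09, 1.07 and 1.07 (camera, adjusted p = 0.21, 0.471 and 0.987), and lysosome and alternative activation lists at 0.94 and 0.926 (0.123 and 0.918). Nppb measured 399 ± 168 CPM with the antimiR and 239 ± 28.5 without it (SD, n = 4 each), a log2 fold change of 0.741 ± 0.253 (SE, edgeR adjusted p = 0.364), with no overlap between the groups. Without antimiR-195 replicate 2 it was 0.403. Nppa stood at −0.15 ± 0.267, and ran from −0.417 (without antimiR-195 replicate 2) to 0.074 (without Upy-PEG replicate 1).

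Inflammatory and macrophage lists were lower with the antimiR too. Macrophage markers fell to a median fold of 0.814 (19 of 20 lower, 7 adjusted over the list alone, camera, adjusted p = 7.09e-06, and 0.546 with an estimated correlation), with Itgam at −0.95 ± 0.227, Adgre1 at −0.69 ± 0.187 and Cd68 at −0.56 ± 0.19 (log2, SE, n = 4 per group). Macrophage fusion genes fell to 0.657 (10 of 10 lower, adjusted p = 8.16e-05, and 0.525 with an estimated correlation), and Atp6v0d2 (−1.14), Gpnmb (−1.01) and Mmp12 (−0.94) passed when adjusted over the list alone. Neutrophil markers fell to 0.648 (adjusted p = 0.00237, and 0.531 with an estimated correlation), with Mmp8 (−1.13) and Csf3r (−0.85) passing when adjusted over the list alone, and monocyte markers to 0.666 (0 adjusted over the list alone, adjusted p = 0.00244, and 0.546 with an estimated correlation). Interferon response genes fell to 0.748 (26 of 28 lower, 0 adjusted over the list alone, adjusted p = 0.000177, and 0.731 with an estimated correlation), complement genes to 0.842 (11 of 12 lower, 0 adjusted over the list alone, adjusted p = 0.00885, and 0.525 with an estimated correlation) and cytokine genes to 0.871 (20 of 24 lower, adjusted p = 0.022, and 0.731 with an estimated correlation), where Il1rn (−1.185) passed when adjusted over the list alone. Matrix proteases fell to 0.841 (17 of 18 lower, adjusted p = 0.000251, and 0.525 with an estimated correlation), with Mmp19 (−0.61) passing when adjusted over the list alone. Myofibroblast genes fell to 0.702 (12 of 14 lower, 0 adjusted over the list alone, adjusted p = 0.00565, and 0.641 with an estimated correlation).

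Many of these falls depended on single libraries. Without Upy-PEG replicate 1 the calls ended for interferon (log2 median −0.05, adjusted p = 0.548), cytokine (−0.05, 0.285) and myofibroblast genes (−0.23, 0.104). Without antimiR-195 replicate 1 they ended for cytokine (−0.06, 0.645), myofibroblast (−0.49, 0.0958) and neutrophil genes (−0.34, 0.0845), and without antimiR-195 replicate 4 for the same lists (−0.17, 0.238; −0.45, 0.0943; −0.65, 0.076). Medians of lists that stayed called moved without Upy-PEG replicate 1 to −0.165 for matrix proteases and −0.37 for monocytes, from −0.25 and −0.586. Without antimiR-195 replicate 2 they moved to −0.424 for cytokines, −0.492 for macrophages and −0.548 for matrix proteases, the first 2 from −0.199 and −0.296. The macrophage median was −0.154 without antimiR-195 replicate 1, and the matrix protease median −0.439 without Upy-PEG replicate 3. In settings chosen after the data were seen, the medians without antimiR-195 replicates 2 and 3 were −0.603 for cytokines, −0.686 for macrophages, −0.999 for macrophage fusion, −0.576 for matrix proteases and −1.382 for neutrophils. With the gene length covariate they were −0.327 for cytokines, −0.533 for macrophages, −1.05 for neutrophils and −0.212 for interferon genes.

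Genes of energy supply and of the working cardiomyocyte rose, as shares of the counts of whole tissue, when the antimiR was added. Nuclear oxidative phosphorylation genes had a median fold of 1.37 with 42 of 42 higher (camera, adjusted p = 6.87e-18, and 0.525 with an estimated correlation), with Uqcrb, of respiratory complex III, at 0.65 ± 0.186 (log2, SE, n = 4 per group). Cardiomyocyte markers rose by 1.33 (17 of 20 higher, adjusted p = 3.44e-06, and 0.525 with an estimated correlation), with the ventricular light chain Myl2 at 0.63 ± 0.195, and fatty acid oxidation genes by 1.18 (24 of 29 higher, adjusted p = 0.000251, and 0.641 with an estimated correlation). Ribosomal protein genes rose by 1.27 (30 of 30 higher, adjusted p = 5.27e-06, and 0.731 with an estimated correlation), heat shock genes by 1.19 (10 of 12 higher, adjusted p = 0.00979, and 0.546 with an estimated correlation) and mitochondrially encoded genes by 1.22 (6 of 7 higher, adjusted p = 0.0235, and 0.693 with an estimated correlation). In these 6 lists, 0 members passed when adjusted over the list alone. Erythroid genes rose by 1.82 (9 of 10 higher, adjusted p = 7.7e-06, and 0.525 with an estimated correlation), and Hba-a1, Hba-a2, Hbb-bs and Alas2 were among those that passed when adjusted over the list alone. Adipocyte markers rose by 2.26 (3 of 3 higher, adjusted p = 0.00492, and 0.525 with an estimated correlation), with Cfd (1.54) and Car3 (1.175) passing when adjusted over the list alone.

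The values of ribosomal protein genes were highest in antimiR-195 replicates 2 and 3, the libraries with the gene length trend. Their mean log2 CPM deviation was −0.156, 0.825, 0.503 and −0.199 in antimiR-195 replicates 1 to 4 and −0.186 to 0.058 with Upy-PEG. Without antimiR-195 replicate 2 the ribosomal call ended (log2 median 0.13, adjusted p = 0.145), and without replicates 2 and 3, an alternative chosen after the data were seen, the list was called lower (−0.155, adjusted p = 0.000205). With the gene length covariate, chosen after the data were seen too, the ribosomal call ended (−0.054, adjusted p = 0.122). Without antimiR-195 replicate 2 the log2 medians of the oxidative phosphorylation, cardiomyocyte and erythroid lists moved from 0.453, 0.412 and 0.863 to 0.292, 0.274 and 0.562, and without Upy-PEG replicate 1 those of the cardiomyocyte and fatty acid oxidation lists moved to 0.274 and 0.123, the latter from 0.239. Without antimiR-195 replicates 2 and 3 the oxidative phosphorylation, cardiomyocyte and erythroid medians were 0.176, 0.249 and 0.375. With the gene length covariate they were 0.162, 0.201 and 0.392, and the fatty acid oxidation median was 0.157. Heat shock genes lost their call without Upy-PEG replicate 2 (log2 median 0.2, adjusted p = 0.0563) or antimiR-195 replicate 4 (0.15, 0.314), and adipocyte markers without antimiR-195 replicate 4 (0.65, 0.064), where Car3 was 0.649. The call of mitochondrially encoded genes ended without Upy-PEG replicate 1 (0.22, 0.0528) and without antimiR-195 replicate 1 (0.19, 0.19) or 3 (0.18, 0.0913).

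**Figure D3:**
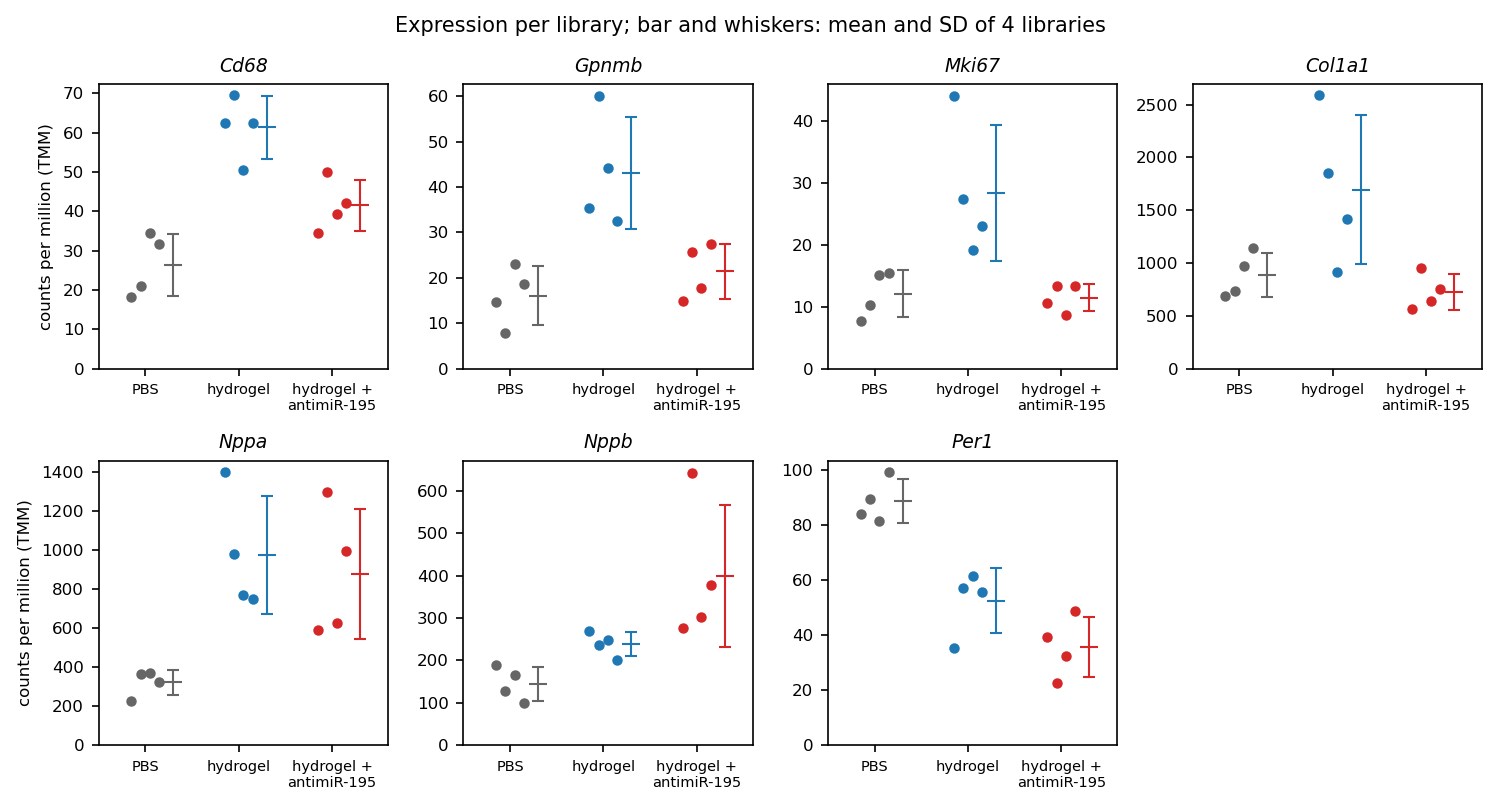
Library-size scaled counts (CPM) of 7 genes in each of the 12 libraries, by group, with the mean and SD of each group of 4. Cd68 averages 26.3 with PBS, 61.4 with Upy-PEG and 41.5 with the antimiR added.

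Between the antimiR-195 group and Upy-PEG edgeR called 0 genes at an adjusted p of 0.05, with a smallest adjusted p of 0.364 and 1930 genes at an unadjusted p under 0.05, 985 higher and 945 lower; DESeq2 called 13 and limma voom with sample weights 0. Groups did not overlap for 650 genes, or 4.4%. The genes of lowest p were Asb5 (0.485), Ppp1r3c (0.35), Atp6ap1l (1.63), Gm20712 (0.65) and mt-Tp (1.27) among the higher, and Csf2ra (−0.68), Pik3ap1 (−1.625), Brca1, Ccnf and Mki67 among the lower, by log2 fold change. Camera called 20 lists, 8 higher and 12 lower, and 11 of them stayed called when any 1 of the 8 libraries compared was left out. No list passed with an estimated correlation (lowest adjusted p 0.525) or with fry (0.253). A 2-sided exact permutation test of each list's mean over the 8 libraries, unadjusted, put 2 of the 45 lists under 0.05. These were complement genes and the miR-195 literature targets, both lower (exact permutation p = 0.0286 each, the smallest the design allows). Mitotic genes stood at an exact permutation p of 0.0571, and extracellular matrix and macrophage genes at 0.143. Among the other 25 lists, adjusted p ran from 0.123 for lysosome genes to 0.987, and the signs of median, mean and test differed for alternative macrophage activation, angiogenesis, clock, dendritic cell, epicardial, glycolysis, ion channel, Schwann cell, sex-linked and T cell genes. Library size alone, in place of TMM normalisation, moved the median of all genes from −0.005 to −0.156 in this comparison. It gave 2701 genes at an unadjusted edgeR p under 0.05, with 5.4% higher against 51%, so the even balance depends on the normalisation. Over the 3 comparisons, 0 of the 57 called lists changed the sign of their median under it, and camera was not run again. In this comparison rises shrank, as for heat shock (0.228 to 0.077) and fatty acid oxidation genes (0.258 to 0.107, medians of log2 CPM differences). Falls grew, as for extracellular matrix genes (−0.601 to −0.752).

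Blocking miR-195 is predicted to raise messages that it holds down, so the values of known targets and of genes with seed sites were compared. Other members of the miR-15 family share the seed, and whether the antimiR blocked them was not measured. The level of miR-195 and the uptake of the antimiR were not measured in these libraries either. The absence of a rise therefore cannot tell these cases from an absent effect. The 22 literature targets fell as a list when the antimiR was added, to a median fold of 0.873 with 16 of 22 lower (camera, adjusted p = 0.0244, 0.546 with an estimated correlation, and 0 adjusted over the list alone). The mean of the list differed by −0.261 log2 between the groups (2-sided exact permutation p = 0.0286, unadjusted over the lists). Cdk1, Birc5 and Nusap1, which drive mitosis, are also in the mitotic list, and without these 3 the median of the other 19 was −0.12 on the log2 scale, with 13 lower. Log2 fold changes were −0.57 ± 0.359 for the checkpoint kinase Chek1, −0.71 ± 0.316 for Cdk1, −0.51 ± 0.277 for Birc5, −0.63 ± 0.276 for Nusap1 and −1.195 ± 0.356 for Spag5 (SE, n = 4 per group). Ccnd1 stood at 0.085, Ccne1 at −0.06, Wee1 at −0.20, Vegfa at 0.10 and Bcl2 at −0.19. Vegfa and Ccnd1 took the other sign under library size alone. That setting moved the median of all genes from −0.005 to −0.156, so the change is not particular to them. Birc5 was −0.318 and −0.836 without antimiR-195 replicates 1 and 2, and Nusap1 −0.364 without Upy-PEG replicate 1. With 1 library left out Ccnd1 ran from 0.022 (Upy-PEG replicate 3) to 0.146 (antimiR-195 replicate 3), Ccne1 from −0.327 (antimiR-195 replicate 2) to 0.095 (antimiR-195 replicate 4) and Wee1 from −0.37 to −0.084 (antimiR-195 replicates 1 and 4). Vegfa ran from −0.02 to 0.2 (antimiR-195 replicates 4 and 2) and Bcl2 from −0.303 (antimiR-195 replicate 4) to −0.062 (Upy-PEG replicate 1). The list lost its call without Upy-PEG replicate 1 (log2 median −0.08, adjusted p = 0.127), antimiR-195 replicate 3 (−0.14, 0.0589) or antimiR-195 replicate 4 (−0.21, 0.0905). In 2 settings chosen after the data were seen, its median of −0.196 shrank further and the call ended: with the gene length covariate (−0.043, adjusted p = 0.16) and without antimiR-195 replicates 2 and 3 (−0.028, 0.137). Between Upy-PEG and PBS its median was 0.01 (adjusted p = 0.109), while Cdk1, Birc5, Nusap1, Spag5 and Cdc42, at 1.23, 1.255, 1.09, 1.27 and 0.32, passed when adjusted over the list alone. With both against PBS the median was −0.05 (adjusted p = 0.717).

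Messages with a seed site did not shift upward with the antimiR. In the 3296 genes with a site for the seed shared by the miR-15 family in the 3' untranslated region, the median log2 fold change against Upy-PEG differed from that of 7242 genes without one by −0.002 (2-sided exact permutation p = 0.857 over 70 assignments of the libraries). Against PBS the shift was −0.037 with the hydrogel alone and −0.044 with the antimiR (exact permutation p = 0.0286 for each, the smallest the design allows). Neither passed with 8mer sites alone (−0.031 and −0.034, exact permutation p = 0.114 and 0.143) or without matching for length (−0.041 and −0.14, exact permutation p = 0.457 and 0.229). For the antimiR against Upy-PEG the shift without matching was −0.078 (exact permutation p = 0.4). With 1 library left out it took either sign, from −0.011 to 0.006. At a mean CPM of at least 10 the shift with the hydrogel alone did not pass (exact permutation p = 0.0571). Of 190 other sequences of the same composition, 190 gave a shift as high as the seed's or higher for the hydrogel alone, 39 for the antimiR against Upy-PEG and 172 for both against PBS. When 1 of the 8 libraries compared was left out, the shift with the hydrogel alone ran from −0.046 to −0.026 and no longer passed in 4 of 8 cases. These were Upy-PEG replicates 1 and 2 and PBS replicate 4 (exact permutation p = 0.0571 each) and PBS replicate 2 (exact permutation p = 0.143). With both against PBS it ran from −0.052 to −0.03 and no longer passed in 5 of 8. These were each antimiR-195 library and PBS replicate 2 (exact permutation p = 0.0571 each). The 35 assignments left allow a p of 0.0286.

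The comparison of the antimiR-195 group with PBS asks what hydrogel and antimiR did together. Stress genes of the heart rose: the hypertrophic list had a median fold of 1.33 with 13 of 16 higher and 7 passing when adjusted over the list alone (camera, adjusted p = 7.86e-07, and 0.428 with an estimated correlation). Nppb measured 399 ± 168 CPM against 145 ± 40.1 with PBS (SD, n = 4 each), a log2 fold change of 1.46 ± 0.257 (SE, edgeR adjusted p = 0.235), and Nppa 877 ± 335 against 322 ± 66, a log2 fold change of 1.45 ± 0.273. Tnfrsf12a, the receptor of the cytokine TWEAK, stood at 0.93 ± 0.176. Genes of the unfolded protein and integrated stress response rose by 1.21 (17 of 21 higher, 6 adjusted over the list alone, adjusted p = 2.08e-05, and 0.428 with an estimated correlation), with the chaperone genes Sdf2l1 at 0.95 and Manf at 0.73. As in the other comparisons, 0 genes passed over all genes in edgeR and 0 lists with an estimated correlation.

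Macrophage, cytokine and lysosome genes were above PBS when the antimiR was present, and other inflammatory lists were not called. Monocyte, neutrophil, complement and interferon lists stood at median folds of 0.967, 1.01, 0.991 and 1.08 (camera, adjusted p = 0.959, 0.947, 0.944 and 0.342), and alternative activation and matrix protease genes at 1.17 and 1.09 (0.191 and 0.382). Macrophage markers rose by a median fold of 1.53 (16 of 20 higher, 11 adjusted over the list alone, camera, adjusted p = 1.36e-05, and 0.771 with an estimated correlation), with Cd68 at 0.66 ± 0.192, Lgals3 at 1.30 ± 0.331 and Ms4a7 at 1.34 ± 0.361 (log2, SE, n = 4 per group), and Adgre1 at 0.22 ± 0.188. Cytokine genes rose by 1.47 (19 of 24 higher, adjusted p = 2.08e-05, and 0.771 with an estimated correlation), and the chemokine genes Ccl3 (1.62), Ccl4 (1.73), Ccl7 (1.30) and Ccl8 (1.77) passed when adjusted over the list alone. Lysosome genes rose by 1.19 (20 of 22 higher, adjusted p = 3.16e-05, and 0.771 with an estimated correlation), with Ctsz, Ctss, Hexa, Gla and Npc2 passing when adjusted over the list alone, macrophage fusion genes by 1.37 (10 of 10 higher, adjusted p = 0.00375, and 0.818 with an estimated correlation), with Trem2 (1.16) passing when adjusted over the list alone, and myofibroblast genes by 1.30 (13 of 14 higher, adjusted p = 0.00399, and 0.828 with an estimated correlation), with Meox1 (1.015) passing when adjusted over the list alone. Mitotic genes rose by 1.17 (31 of 35 higher, 0 adjusted over the list alone, adjusted p = 0.0108, and 0.947 with an estimated correlation), and Mki67 averaged 11.5 ± 2.23 CPM against 12.1 ± 3.8 with PBS (SD, n = 4 each). Extracellular matrix genes were not called, at a median fold of 1.07 (adjusted p = 0.191), with Col1a1 at −0.29 ± 0.274 and Postn at 0.91 ± 0.359. The fusion call ended without PBS replicate 1 (log2 median 0.4, adjusted p = 0.0511), the myofibroblast call without antimiR-195 replicate 2 (0.2, 0.0509), and the mitotic call without PBS replicate 1 (0.11, 0.328) or 2 (0.11, 0.171) or antimiR-195 replicate 2 (0.06, 0.406) or 4 (0.22, 0.0647). Without PBS replicate 4 the mitotic median was 0.334. Without antimiR-195 replicate 2 the macrophage, cytokine and lysosome medians moved from 0.612, 0.558 and 0.253 to 0.328, 0.354 and 0.155. Without that library Ms4a7 was 0.832, Ccl4 0.932, Trem2 0.728, Postn 0.453, Col1a1 −0.451 and Adgre1 0.123. Without PBS replicate 4 Col1a1 was −0.145 and Adgre1 0.351. Without antimiR-195 replicate 1 they were −0.192 and 0.337. Without PBS replicate 2 Adgre1 was 0.143. Without antimiR-195 replicates 2 and 3, a setting chosen after the data were seen, the calls ended for cytokine (0.222, adjusted p = 0.0569), macrophage fusion (0.177, 0.264), myofibroblast (0.204, 0.0648) and mitotic genes (0.075, 0.281). The macrophage and lysosome medians were then 0.134 (adjusted p = 0.0193) and 0.104 (0.0463). With the gene length covariate these 2 medians were 0.25 and 0.131.

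Ribosomal protein genes had the lowest p in this comparison, rising by 1.42 with 30 of 30 higher and 13 passing when adjusted over the list alone (camera, adjusted p = 8.25e-13, and 0.771 with an estimated correlation). Their log2 median of 0.511 moved to 0.299 without antimiR-195 replicate 2, and to 0.053 (adjusted p = 0.232) without replicates 2 and 3, an alternative chosen after the data were seen. With the gene length covariate, chosen then too, it was 0.063 (adjusted p = 0.00721). Oxidative phosphorylation genes rose by 1.20 (35 of 42 higher, 0 adjusted over the list alone, adjusted p = 0.000557, and 0.947 with an estimated correlation), but their call ended without antimiR-195 replicate 2 (0.1, 0.0593) or without replicates 2 and 3 (−0.03, 0.791). Their median took the other sign with each library's gene length slope as a covariate (−0.105, adjusted p = 9.48e-05). Clock genes fell to 0.867 (13 of 17 lower, adjusted p = 4.19e-05, and 0.428 with an estimated correlation), and Per1, Per2, Per3, Cry2 and Hlf passed when adjusted over the list alone. Per1 measured 35.7 ± 11 CPM against 88.5 ± 8.02 with PBS (SD, n = 4 each), a log2 fold change of −1.31 ± 0.212 (SE, edgeR adjusted p = 0.235). The clock median of −0.206 moved to −0.334, −0.351 and −0.376 without antimiR-195 replicates 1, 3 and 4 in turn. Ion channel genes fell to 0.874 (20 of 26 lower, 0 adjusted over the list alone, adjusted p = 0.0101, and 0.854 with an estimated correlation), with Kcnh2 at −0.33. They lost their call without antimiR-195 replicate 2 (−0.14, 0.114), without replicates 2 and 3 (−0.02, 0.998) or with the gene length covariate (0.011, 0.876).

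Between the antimiR-195 group and PBS edgeR called 0 genes at an adjusted p of 0.05, with a smallest adjusted p of 0.235 and 2444 genes at an unadjusted p under 0.05, 1278 higher and 1166 lower; DESeq2 called 45 and limma voom with sample weights 1. Groups did not overlap for 895 genes, or 6.1%. Library size alone, chosen after the data were seen, gave 2299 genes at an unadjusted edgeR p under 0.05, with 33.9% higher against 52.3%. By lowest p the higher genes were Nppb, Apobec1 (0.81), Myl1 (0.67), Wfdc17 (1.75) and Lipo3 (0.54), and the lower ones Per1, Ing5 (−0.64), Sh2d3c (−0.51), Itpr3 (−0.77) and Gm20721 (−0.77). Camera called 12 lists, 10 higher and 2 lower, of which 7 stayed called when any 1 of the 8 libraries compared was left out, and fry called none (lowest adjusted p 0.0716). The exact permutation test of list means, unadjusted, put 5 of the 45 lists under 0.05. The other 33 lists had adjusted p from 0.0635 for skeletal muscle to 0.959, and the signs of median, mean and test differed for complement, erythroid, immediate early, lymphatic, monocyte and Schwann cell genes.

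The effects of the 2 hydrogel groups against PBS had a positive covariance with no PBS library shared. With all libraries, across 14770 genes the log2 fold changes had a Pearson r of 0.551 and a covariance of 0.0625, against 0.498 and 0.0294 in 20 simulations of unchanged groups sharing PBS libraries. The jackknife SE of r over libraries was 0.202, above its distance from the simulated value. Without 1 library r ran from 0.473 to 0.659 and the covariance from 0.0456 to 0.0814. With the PBS libraries split between the comparisons, so that none was shared, r was 0.307 and the covariance 0.0388, and the separate arrangements ran from 0.0153 to 0.0566. The effect of the hydrogel and the effect of adding the antimiR had a negative covariance, while their r depended on the arrangement. With all libraries the covariance was −0.0479, against −0.0284 in the simulations, but r, at −0.452, was less negative than the simulated −0.485 (−0.511 to −0.461). With the Upy-PEG libraries split in the same way, a comparison added after the data were seen, their covariance was −0.024 (arrangements −0.0379 to −0.013), with an r of −0.198. Genes are not independent replicates, so no p is given for these values. The simulations drew each gene independently, so their ranges leave out correlation between genes.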

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

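Of the tests in this part, those on a few abundant genes, on Upy-PEG replicate 1, on the gene length trend of the first component and of the lists, on harvest time, on list-level covariance and without antimiR-195 replicates 2 and 3 were chosen only after the result was seen.

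In 441 groups of 4 libraries (135 genes, 8 lists and 4 library measures), 24 held a library farther from the rest than Dixon's critical value for 4 values allows, where chance gives 22.1. In PBS replicate 1, mitochondrially encoded genes took 12.3% of counts (other PBS libraries 18.7% to 19.5%), and mt-Nd1 measured 19900 CPM (29400 to 31200), Cox7a1 1040 (564 to 635), Hba-a1 240 (78.3 to 99.1), Hba-a2 208 (62 to 81), Hbb-bs 838 (283 to 367) and Il4ra 26.2 (31.6 to 32.6). PBS replicate 2 had Pcna at 20.6 CPM (25.1 to 25.7 in the other PBS libraries). PBS replicate 3 had Alcam at 3.66 CPM (2.67 to 2.8), Kcnn2 at 23.8 (19.6 to 20.3), Il6 at 1.21 (0.255 to 0.358) and Mmp12 at 4.83 (2.15 to 2.51), and PBS replicate 4 had Il1b at 3.78 (1.7 to 1.99). Upy-PEG replicate 1 had interferon response genes at 1.08 on the log2 scale (−0.131 to 0.076 in the other Upy-PEG libraries), Dhx58 at 12.4 CPM (5.16 to 5.95), Kif20a at 14.5 (7.78 to 8.39), Ccnf at 4.97 (3.01 to 3.33) and Asb5 at 15 (17.9 to 18.4). Among the other Upy-PEG libraries, replicate 2 had Gla at 9.58 CPM (7.79 to 8.09) and Chil3 at 8.99 (7.86 to 8.02), and replicate 4 had Cfp at 29.2 (24.4 to 24.9) and Retnla at 1.85 (1.18 to 1.26). With the antimiR, replicate 2 had Rapgef3 at 25.6 CPM (28.3 to 28.9) and replicate 4 had Arntl at 13.6 (2.15 to 3.48).

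Alignments of multi-mapped reads, which no gene count uses, came to 0.805 ± 0.123 per counted read in the antimiR-195 libraries, above 0.641 ± 0.0262 with PBS (SD, n = 4, 2-sided exact permutation p = 0.0571, 0.129 after Benjamini-Hochberg adjustment over the 3 comparisons). Replicates 2 and 3 stood highest, at 0.921 and 0.893.

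AntimiR-195 replicates 2 and 3 stood apart from the other 10 libraries on the first principal component, at −60.2 and −40.7 (others −8.5 to 33.4), while their root mean square deviations of 0.545 and 0.451 log2 lay on either side of the 0.465 of Upy-PEG replicate 1. A few genes taking most of the counts was argued against, since the share of the 10 most abundant genes lay inside the range of the other 10 libraries in 2 of 2 (20.76% and 26.3%, against 19.97% to 27.74%). A gene length trend as the whole of the first component was argued against, since with the trend removed they stood at −52.5 and −34.1, at least 2.48 SD of the other 10 below these (−5.1 to 33.1). The trend held 21.7% and 11.9% of their variance and stays open as a part. The deviations left, 0.482 and 0.423, decide nothing for replicate 3, at a ratio of 0.95 to Upy-PEG replicate 1 (0.446), since it lay below that library beforehand. Whether the antimiR acted in those hearts alone stayed open: their seed site shifts against the PBS mean were −0.049 and −0.036, and the Upy-PEG libraries averaged −0.038 ± 0.011 (SD, n = 4). RNA quality was not measured in the sources used, so a technical and a biological origin cannot be told apart.

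The 11 lists that rose with the hydrogel and fell with the antimiR were complement, extracellular matrix, cytokine, interferon, macrophage, macrophage fusion, matrix protease, mitotic, monocyte, myofibroblast and neutrophil genes. With the Upy-PEG libraries split so that none was shared, the covariance was −0.024 across genes. Across the 45 lists it was −0.0915 (−0.103 to −0.0673, 6 of 6 arrangements below 0). These values go against sharing as the whole cause but do not exclude chance structure among the libraries. The arrangements reuse the same libraries, and the spread that chance gives with correlated genes was not measured. Upy-PEG replicate 1 as the whole cause was argued against by 8 of the 11 lists still called lower without it, and a gene length trend by 11 of 11 with the length slope as a covariate. With an estimated correlation or with fry 0 of the 11 were called lower, and without antimiR-195 replicate 1 or 4 it was 8. An effect of the antimiR stays open as a hypothesis, untested beyond these values, and splits were counted only for all 20 lists called between these groups (7 of 35 gave as many), not for the 11.

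Clock genes were lower than PBS in both hydrogel groups, and hearts taken at different hours are a candidate explanation. The opposite arm was the mean of Dbp, Tef, Per2, Per3, Nr1d1, Nr1d2, Hlf and Ciart, without Per1. It differed from PBS by −0.57 log2 in each hydrogel group (2-sided exact permutation p = 0.0286 each). The morning arm of Arntl, Npas2 and Clock stood at 0.54 with Upy-PEG and 0.22 with the antimiR (exact permutation p = 0.2 and 0.8). Within groups, as a time difference predicts, the arms ran against each other over the 12 libraries, with a Pearson r of −0.79 (permutation p = 0.0286) and a Spearman rho of −0.531 (permutation p = 0.173). Without Upy-PEG replicate 1 and antimiR-195 replicate 4 r was −0.381 (permutation p = 0.361), so the relation rests on those libraries. Per1, left out of the arm, followed it only in part. In Upy-PEG replicate 1 Per1 (35.05 CPM) and the arm (−0.5 log2 from the group mean) were both the lowest of their group. With the antimiR, Per1 was highest in replicate 4 (48.53 CPM), where the arm was lowest (−0.65). The labels give no harvest time, so time and group cannot be told apart.

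Other splits of the same 8 libraries into 4 and 4 were counted for each comparison. At an adjusted p of 0.05 edgeR called 0 genes in every comparison, a count that each of 35 splits reaches by construction, so it says nothing about chance. The highest other counts were 1 for Upy-PEG against PBS, 0 for the antimiR-195 group against Upy-PEG and 1216 for it against PBS; unadjusted counts and those of DESeq2 and limma stand in the report. At an unadjusted p under 0.05, 1 of 35 splits of Upy-PEG against PBS, the real one, gave 1944 genes and the highest other 1807. That is the highest rank the design allows, and it was not adjusted for the other counts. It goes against chance as the source of this count without excluding it. Chance could not be excluded for the antimiR-195 group against Upy-PEG (1930 genes, 6 of 35, highest other 3815) or against PBS (2444 genes, 6 of 35, highest other 5062). For lists called it could not be excluded in any comparison: 25 lists, 4 of 35 and 27 for Upy-PEG against PBS; 20 lists, 7 of 35 and 22 for the antimiR-195 group against Upy-PEG; 12 lists, 18 of 35 and 25 for it against PBS. The split with 5062 and 1216 genes put PBS replicate 1 with antimiR-195 replicates 1, 2 and 3, which points to a structure among samples that the groups do not follow.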

How the results depend on the processing

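Of the settings here, leaving out antimiR-195 replicates 2 and 3, the gene length covariate and offset, library size alone, the upper quartile and the split of the Upy-PEG libraries were chosen only after the results were seen. For Upy-PEG against PBS, 0 genes became 69 with no filter on low counts, 518 with DESeq2, 918 with limma voom with sample weights, 172 with only the 8 libraries compared, 349 without antimiR-195 replicates 2 and 3, 332 with the gene length slope as a covariate, 155 at an adjusted p under 0.10, and 0 to 46 with 1 of the 8 libraries compared left out (46 without Upy-PEG replicate 3). With RLE size factors, a mean CPM of at least 1, limma-trend on RPKM, both hydrogel groups together, a length offset, library size alone or the upper quartile it stayed at 0. For the antimiR-195 group against Upy-PEG, DESeq2 called 13 genes and every other setting 0. Against PBS, DESeq2 called 45, no filter 1 and limma voom 1, and every other setting 0. Apart from the looser threshold, the cause was not tested.

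The 25, 20 and 12 lists called became 0, 0 and 0 with camera and an estimated correlation, and 7, 0 and 0 with fry. With 1 of the 8 libraries compared left out the counts ran from 22 to 27, 14 to 21 and 10 to 16. Without antimiR-195 replicates 2 and 3 they were 22, 23 and 8, with 5 of the 12 against PBS kept, and with the gene length covariate 24, 20 and 19, with 10 of the 12 kept. Changes of direction were seen for ribosomal genes against Upy-PEG without antimiR-195 replicates 2 and 3 (log2 median −0.155) and for oxidative phosphorylation genes against PBS with the gene length covariate (−0.105), both still called. Medians also changed sign where the call ended, for ribosomal genes against Upy-PEG with the covariate (−0.054), and against PBS for oxidative phosphorylation genes without replicates 2 and 3 (−0.03) and ion channel genes with the covariate (0.011); the cause was not tested.

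The seed site shift of Upy-PEG against PBS no longer passed with 8mer sites (−0.031), without length matching (−0.041) or at a mean CPM of at least 10 (−0.033), and ran from −0.046 to −0.026 with 1 library left out, no longer passing in 4 of 8 cases. With both against PBS it no longer passed with 8mer sites (−0.034), without length matching (−0.14) or without antimiR-195 replicates 2 and 3 (−0.035, where 15 assignments cannot reach 0.05), and ran from −0.052 to −0.03 with 1 library left out, no longer passing in 5 of 8 cases. For the antimiR against Upy-PEG it ran from −0.011 to 0.006 with 1 library left out and was −0.078 without length matching (exact permutation p = 0.4); the cause was not tested. The correlation of the hydrogel effects was 0.307 with the PBS libraries split and that of the hydrogel and antimiR effects −0.198 with the Upy-PEG libraries split, from 0.551 and −0.452. A split removes shared libraries and leaves fewer in each comparison, and these were not separated. Of the named genes, 3 of 99, 12 of 84 and 9 of 60 took the other sign under at least 1 setting, for Upy-PEG against PBS, the antimiR-195 group against Upy-PEG and against PBS in turn. At this depth and group size, neither of which was varied, the simulated recovery of 1.5-fold changes was 25.4%, 19.4% and 25.4%. Genes were drawn independently there, so recovery in the real data was not measured.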
